A study of Mus musculus with 12 samples.

How the data were processed

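The series compared mouse mammary tumors labelled ShcA-null with a pooled reference made from NIC mammary tumors. ShcA, encoded by Shc1, is an adaptor protein that links receptor tyrosine kinases to Ras and MAP kinase signalling. NIC tumors are driven in the mammary epithelium by an activated Neu (ErbB2) receptor that is expressed together with Cre recombinase. Each array was a two-colour Agilent whole mouse genome oligonucleotide array, on which the RNA of 1 tumor and the pooled reference RNA were hybridised together. There were 12 arrays of 8 tumors. On the first array of every tumor the tumor RNA carried Cy5 (red), and tumors 1 to 4 had a second array on which the dyes were swapped, so that the tumor RNA carried Cy3 (green). Per the labels' protocols, total RNA was isolated with an RNeasy Midi kit, and 500 ng was amplified by 1 round of T7 linear amplification with amino allyl nucleotides. The labels give no age, strain or number of animals behind the pool, and do not state which part of Shc1 was deleted.

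Per the file headers, spots were quantified with Agilent Feature Extraction 9.5.3.1 on an array design whose probe coordinates refer to the mouse build mm7. The mean foreground intensity and the median local background intensity of each spot, in both channels, were deposited without normalization. Feature Extraction's processed intensities, per the file headers, had been background-subtracted, detrended and dye-normalized within each array by a linear and a lowess step. The deposited log10 ratio of each spot is red over green of those processed signals, per the file headers. The deposited flags, other values of 0 or 1 per spot, mark spots that were well above background, saturated or outliers. The authors also deposited a value table on the log2 scale. Set against the scanner log ratio over 43370 features, its slope lay between 0.758 and 0.797 on the 8 first arrays and between -0.748 and -0.715 on the 4 swapped arrays, so its columns are already turned to tumor over reference. Its correlation with the ratios used here was 0.826 for the swapped array of tumor 1 and at least 0.928 on the other arrays. The medians of its columns were 0, 0.00575, -0.0715, -0.00668, -0.0252, 0.137, 0.115 and 0.000792 for the first arrays of tumors 1 to 8, and -0.0124, -0.0508, -0.00659 and -0.00298 for the swapped arrays. How these values were normalized and centred is not given in the sources used here, and they served only as an alternative.

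Each array held 43379 gene spots and 1639 control spots. Background was corrected by normexp with an offset of 50 on the mean foreground and median background intensities, and each array was normalized by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3 with the R package data.table (1.17.8). Spots with an outlier flag were left out (0.47% to 13.7% of the gene spots of an array, the most on the first array of tumor 1), and saturated spots were kept (at most 3 on an array). The log2 ratio was turned to tumor over reference on every array, spots of one probe were averaged, and both arrays of a tumor were averaged, so that the tumor is the replicate (n = 8). Of 41174 gene probes, 30838 were kept because either channel was well above background on at least 1 array of at least 4 tumors. Probes were named through the accession in the file (22951 probes), the symbol (6659) or an older symbol (3109) through RefSeq names of assembly GRCm38.p6, and 8455 kept the name in the file. A gene with several kept probes was represented by the probe with the highest mean intensity, which left 20341 genes. For 79 named genes, 24 had more than 1 kept probe, and for 1 (B2m) a kept probe had the opposite sign.

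The pool is the control RNA, and no control tumor was hybridised on its own. It therefore counts as 1 control sample: the mean log2 ratio was tested against 0 with limma (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05), and this test leaves out the spread between control tumors. It cannot tell a difference of the tumors labelled ShcA-null from a peculiarity of that 1 pool. A count with an added threshold of 2-fold (a mean log2 ratio of at least 1 in size) was made beside it. The labels number the tumors separately but do not say that they came from separate animals, so the p-values measure the spread between these 8 samples. The swapped dye cancels a dye effect in tumors 1 to 4 only. A fit of all 12 arrays with a dye term and the tumor as a random block was therefore an alternative. The files give 3 slides: first arrays of tumors 1 to 4, first arrays of tumors 5 to 8, and the 4 swapped arrays. Slide and dye orientation cannot be told apart for the swapped arrays.

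Gene lists (35, with 5 or more tested members each) and the rule for named genes were fixed before the data were examined. The rule takes Shc1 and Erbb2; the 10 genes with the largest positive and the 10 with the largest negative mean among those with an adjusted p under 0.05 both in the 8-tumor fit and in the fit with a dye term, one sign in all 8 tumors and a plain gene symbol; and up to 3 called members with the largest ratios from each list that passed its set test and from 9 lists on adaptive immunity, antigen presentation, interferon, ERK and luminal epithelium. Other called members are named where a list had few, and were chosen after their values were seen. Lists were tested against all other genes with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it. Missing values (1.26%) were set to the gene's mean for these tests. The median of each list in each tumor was also tested with an exact two-sided sign-flip test over the 8 tumors, whose smallest p is 0.00781. Genes of one family that share sequence, such as immunoglobulin segments, keratins and histocompatibility genes, can cross-hybridise, and their values are uncertain to that extent.

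The signal, not a read count, sets the depth: between 63.5% and 77.6% of the gene spots of an array were well above background in the tumor channel, and between 68.2% and 74.7% in the reference channel. The number of arrays limits the precision. On simulated data with the spread of the 20341 real genes over 8 tumors, the limma fit called 13.4% of 67 genes changed by a log2 ratio of 0.5, 55.2% of 67 changed by 1 and 97% of 66 changed by 2, and 5 unchanged genes. Camera called 3 of 3 shifted lists, and 0 lists when nothing was shifted. The simulated genes were drawn independently, whereas the estimated correlation within a list reached 0.664 here. These counts therefore say nothing about false calls of camera among correlated genes. A step that matches each swapped array to a first array by the correlation of deviations placed 400 of 400 simulated arrays. The simulated tumors were independent of one another, whereas real first arrays correlated at up to 0.80, so the real task may be harder. Alternatives fixed before the data were examined were no background correction, an offset of 16, Feature Extraction's processed signals, Aquantile, median centring, the authors' value table, other filters and probe rules, dye terms, subsets of arrays, other variance moderation, array weights, a stricter threshold, the slide as a block and each tumor left out. After the data were seen, pairing of the swapped arrays by best match, alone and with a dye term, and a fit without tumors 6 and 7 were added. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.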

Results

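Expression was measured in 8 mouse mammary tumors labelled ShcA-null against a pool of NIC tumors, on 12 two-colour arrays. Shc1 encodes ShcA, the adaptor through which ErbB receptors and other tyrosine kinases reach Ras and the MAP kinases. Erbb2 is the mouse gene of the ErbB2 (Neu) receptor, an activated form of which drives NIC tumors. Neither was called different from the pool over the 8 tumors. The 1 kept Shc1 probe (A_52_P384250, accession NM_011368 in the file, mm7 chr 3: 89556207-89556266) gave a mean log2 ratio of 0.12 ± 0.65 (SD, n = 8), with an exact sign-flip p of 0.617 and a limma adjusted p of 0.728 over all probes. It was well above background on 12 of 12 arrays in both RNAs. On the first arrays of tumors 1 to 8 its log2 ratio was 0.33, -0.03, -2.05, 0.58, 0.71, 0.24, 0.52 and 0.30, and on the swapped arrays labelled tumors 1 to 4 it was 0.59, -2.22, 0.74 and 0.45. The label is therefore not borne out by Shc1 RNA in most tumors. The labels do not give the deleted part of the gene, and if the probe lies outside it, it checks nothing. The 2 Erbb2 probes (accession NM_001003817 in the file, mm7 chr 11) gave 0.13 ± 0.68 (A_52_P49250, 98545828-98545887, exact sign-flip p of 0.57) and -0.40 ± 1.31 (A_51_P216179, 98543549-98543608, exact sign-flip p of 0.438; SD, n = 8). They differed most in tumor 7 (0.36 and -2.60). Both are assigned to the mouse transcript, and whether they also detect the activated Neu is not given. They may therefore not measure the driver of these tumors.

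**Figure D1:**
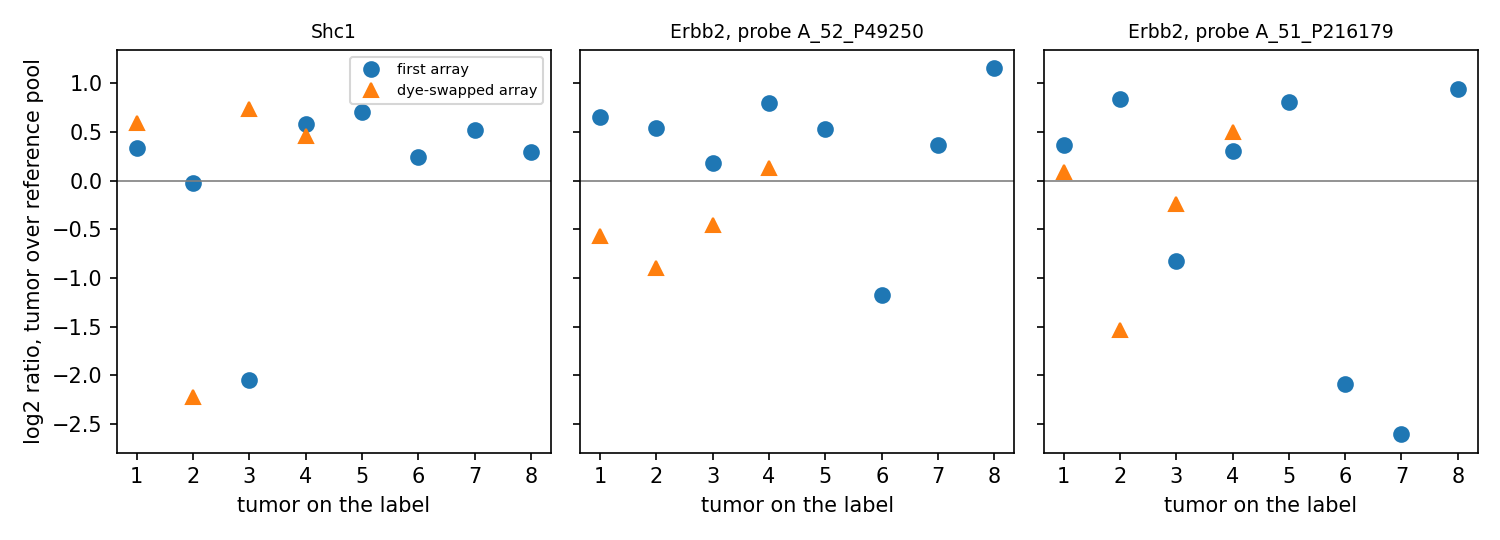
Log2 ratio of tumor over reference pool for the Shc1 probe and both Erbb2 probes on each of the 12 arrays, first and swapped arrays drawn apart. Shc1 lay far below the pool on the first array of tumor 3 (-2.05) and on the swapped array labelled tumor 2 (-2.22).

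Milk-protein genes were among the highest: Csn1s1 encodes a casein, Wap the whey acidic protein, and Glycam1 a mucin-like protein of milk. So were immune genes, among them Jchain, which joins IgA and IgM chains, a kappa variable segment of the Igkv1 group, the interferon-induced GTPase gene Gbp2b and the acute-phase gene Saa2. Among the genes furthest below the pool were the X-linked Xlr3c, Tfap2b of the AP-2 transcription factors, the lipid kinase gene Pik3c2g and the homeobox gene Hoxb2. Csn1s1 was 19-fold higher (4.25 ± 1.02, SD, n = 8; limma adjusted p = 0.000179), followed by Dmrta2 (3.28 ± 0.31), Jchain (2.88 ± 0.63), Glycam1 (2.87 ± 0.71), Wap (2.84 ± 1.02), Gbp2b (2.77 ± 1.34), the fatty-acid carrier gene Fabp3 (2.47 ± 0.56), the Igkv1 segment (2.26 ± 1.10), Lcn10 (2.23 ± 1.12) and Saa2 (2.22 ± 0.79; SD, n = 8 for each). Xlr3c was 12.5-fold lower (-3.65 ± 0.63; limma adjusted p = 5.01e-05), and Tfap2b 10.7-fold lower (-3.43 ± 0.63; limma adjusted p = 7.05e-05). The size for Tfap2b depends on the probe, since its 2 other kept probes gave -1.09 and -1.10. Then came Pik3c2g (-3.05 ± 0.79), Odam (-3.03 ± 1.26), Naaladl2 (-2.95 ± 1.04), Dnajc6 (-2.92 ± 1.21), Sec14l4 (-2.89 ± 0.34), Dpyd (-2.74 ± 1.78), Scgb1b27 (-2.72 ± 0.98) and Hoxb2 (-2.71 ± 0.88; SD, n = 8 for each). All 20 had one sign in every tumor and kept an adjusted p under 0.05 in a limma fit with a dye term and swapped arrays paired by best match. Tumor 5 lay near the pool for Odam (-0.22) and Scgb1b27 (-0.46). Pik3c2g turned to 1.00 (limma adjusted p = 0.0501) with outlier spots kept, when another, brighter probe represented it.

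**Figure D2:**
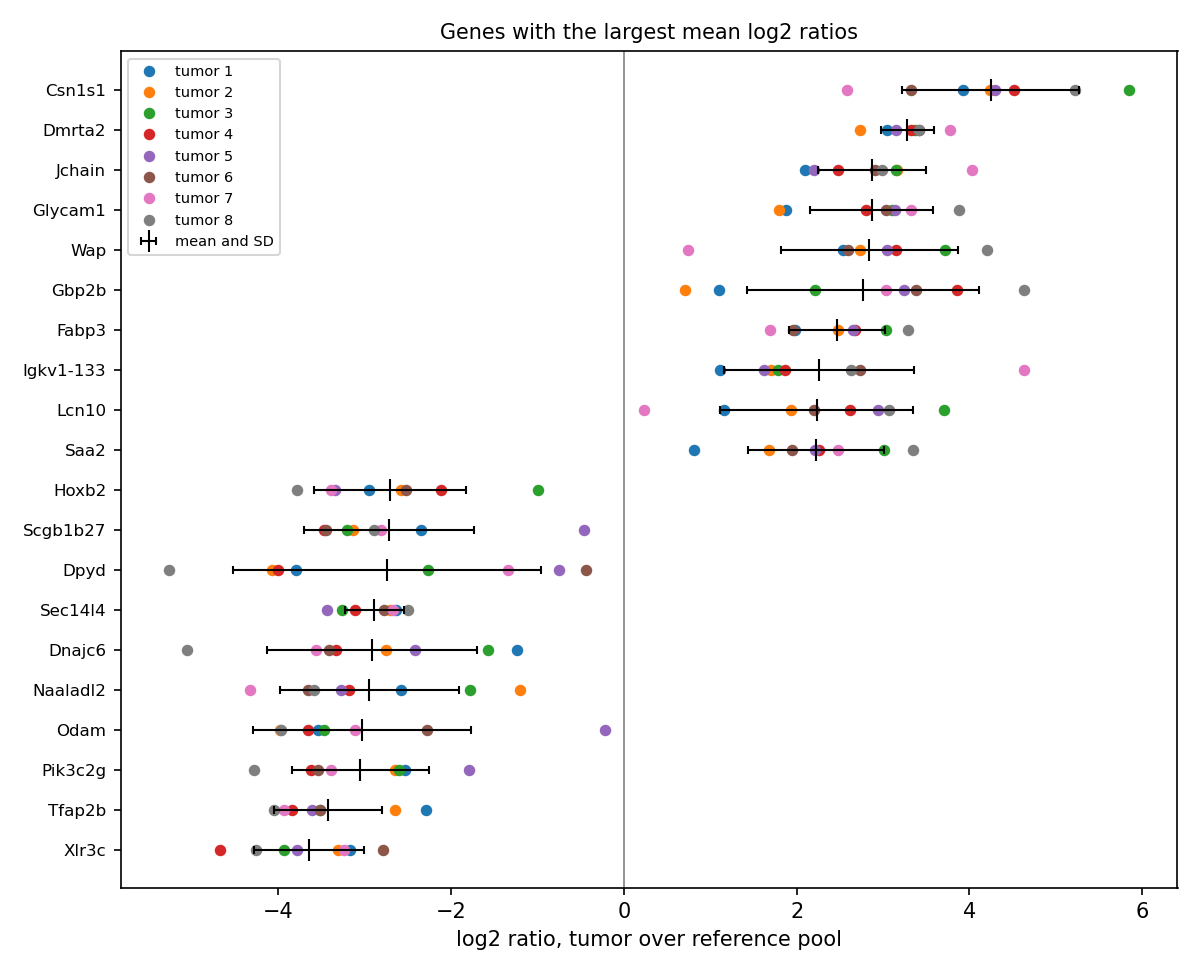
Log2 ratio of tumor over reference pool in each of the 8 tumors for the 10 highest and 10 lowest named genes. Csn1s1 (mean 4.25) and Xlr3c (mean -3.65) lay at the ends, and tumor 5 stood apart for Odam (-0.22) and Scgb1b27 (-0.46).

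Of 20341 genes tested, 3499 passed a limma adjusted p of 0.05, of which 1341 were higher (38.3%) and 2158 lower. Median centring in place of loess put 71.1% of the called genes higher, and moved the median log2 ratio of all genes from -0.02 to 0.16, so the balance of higher and lower genes rests on the scaling. Past a 2-fold mean change there were 964 genes, 381 higher, such as Csn1s1, and 583 lower, such as Xlr3c. At an unadjusted p under 0.05 there were 6761 genes, and 2928 had one sign in all 8 tumors. Signs drawn at random would give 0.781% of genes, but all ratios share 1 pool, so this share is no measure of what chance gives here. Without tumor 4 the count of called genes was 1971, and without tumor 8 it was 2239. The fit with a dye term and best-matching pairs called 1636 genes, 618 of them past 2-fold. Of the 3499 genes, 1439 were among these with the same sign, for example Jchain, Dmrta2, Tfap2b and Sec14l4. The p-values measure the spread between tumors and leave out that of the control, which is 1 pool.

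Some genes of T cells and their regulation were higher in the tumors labelled ShcA-null, although most of the T cell list was not called: Lck, the kinase that starts T cell receptor signalling, Il18r1 and Cxcr6 of the interferon-gamma producing T helper 1 cells, the checkpoint gene Lag3, and Cd274 (PD-L1), a checkpoint ligand that many cell types carry. Gata3, which directs T helper 2 cells and is also a luminal epithelial factor, was called lower, but not with median centring. The T helper 1 list stood highest of these: 7 of 10 tested members were higher and 3 were not called (10 adjusted over the list alone), with Il18r1 at 1.83 ± 0.94, Cxcr6 at 1.07 ± 0.81 and Cxcr3 at 1.00 ± 0.80 (SD, n = 8) and a list median of 0.75. The T helper 1 list passed camera with an adjusted p of 1.59e-05 (adjusted p = 0.417 with an estimated correlation). In a limma fit with the dye term and best-matching pairs 5 of its genes were called higher. Of 16 tested regulatory T cell and checkpoint genes, 8 were higher and 8 not called (10 higher and 1 lower adjusted over the list alone), with Lag3 at 1.18 ± 0.81, Icos at 1.10 ± 0.98 and Cd274 at 1.00 ± 0.44 (SD, n = 8). A second Icos probe gave 1.08 (limma adjusted p = 0.109). With the dye term and best-matching pairs only 3 of the 16 were called higher, and 1 lower, by limma. The regulatory T cell and checkpoint list passed camera with an adjusted p of 0.000202 (adjusted p = 0.417 with an estimated correlation). Of 15 tested T cell genes, Lck was higher (1.51 ± 0.92, n = 8), Cd3e called lower (-0.996 ± 0.446, n = 4) and 13 not called (7 higher and 1 lower adjusted over the list alone), with a list median of 0.74. The T cell list passed camera with an adjusted p of 0.00329 (adjusted p = 0.464 with an estimated correlation). No direction can be given for Cd3e, a part of the T cell receptor complex. It was measured in tumors 1 to 4 only, stood at -0.11 (limma adjusted p = 0.813) with the dye term and best-matching pairs, and turned to 1.01 (limma adjusted p = 0.0479) with outlier spots kept. Its mean level over all arrays was higher in the tumors (log2 of 11.99) than in the reference (10.98). Of 10 tested T helper 2 genes, Chil3 was higher (1.04 ± 0.45), Gata3 lower (-0.73 ± 0.41; SD, n = 8) and 8 not called (2 higher and 1 lower adjusted over the list alone). The T helper 2 list passed camera with an adjusted p of 0.0423 (adjusted p = 0.417 with an estimated correlation). The T helper 2 call was lost in 14 of the alternative fits, and Gata3 stood at -0.08 (limma adjusted p = 0.808) with median centring and had a limma adjusted p of 0.0666 with the dye term and best-matching pairs. Of 14 tested cytotoxic T and NK cell genes, chosen here after their values were seen, Gzmk (0.47) and Ccl5 (1.09) were higher, Gzmb lower (-0.98 ± 0.55, SD, n = 8) and 11 not called (camera adjusted p = 0.106). Gzmk had a limma adjusted p of 0.202 with the dye term and best-matching pairs and of 0.144 with median centring. The T cell list median was 3.00 in tumor 7 and between 0.11 and 0.575 in the others. With median centring the T cell list had a camera adjusted p of 0.0734, at a list median of 0.79.

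Some antibody genes and genes of organized lymphoid tissue were higher, among them Mzb1, a chaperone of plasma cells, Cxcl13 and Ccl19, which draw B cells and T cells into lymphoid follicles and zones, and Il7r, the receptor for a lymphocyte survival factor. Of 10 tested plasma cell and immunoglobulin genes, 5 were higher and 5 not called (6 adjusted over the list alone): Jchain, Mzb1 (1.43 ± 0.91) and Ighg1 (1.30 ± 0.86; SD, n = 8), and, chosen after their values were seen, Prdm1 (0.64) and Igh (0.59). The size for Ighg1 depends on the probe, since its 2 other kept probes gave 2.23 and 2.61. Igh had a limma adjusted p of 0.168 with the dye term and best-matching pairs and of 0.0838 with median centring. The plasma cell list passed camera with an adjusted p = 0.00121 (adjusted p = 0.417 with an estimated correlation). Of 9 tested lymphoid organ genes, Cxcl13 (2.35 ± 1.33), Ccl19 (1.42 ± 1.04) and Il7r (1.38 ± 0.94; SD, n = 8) were higher and 6 not called (5 higher adjusted over the list alone). A second Il7r probe gave 0.51 (limma adjusted p = 0.152). The lymphoid organ list passed camera with an adjusted p of 0.000863 (adjusted p = 0.417 with an estimated correlation). Of 10 tested B cell genes, Cd72 was higher (0.91 ± 0.44, SD, n = 8) and 9 not called (1 higher adjusted over the list alone), with a list median of 0.57 and a camera adjusted p of 0.00729 (adjusted p = 0.464 with an estimated correlation). The B cell call was lost with median centring (list median of 0.56, camera adjusted p = 0.0734). It was also lost with the filter that asks for both channels on every array (list median of 0.415, camera adjusted p = 0.0717). In tumor 7 the median was 2.70 for the plasma cell, 2.79 for the lymphoid organ and 2.88 for the B cell list, against 0.24 to 0.91, 0.10 to 1.11 and 0.11 to 0.69 in the others.

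Some genes of antigen presentation and of the chemokines that bring in T cells were higher. Cd74 is the invariant chain that guides MHC class II molecules, H2-Ab1 one of those molecules, and Cxcl9, Cxcl10 and Cxcl11 are interferon-induced ligands of Cxcr3. Of 32 tested chemokine genes, 10 were higher, 1 lower (Ccl27a at -0.40 ± 0.23, chosen after its value was seen) and 21 not called (14 higher and 1 lower adjusted over the list alone), led by Cxcl13, Cxcl9 (1.95 ± 0.72) and Cxcl10 (1.86 ± 0.37; SD, n = 8). The chemokine list passed camera with an adjusted p of 0.000105 (adjusted p = 0.417 with an estimated correlation). Of 11 tested MHC class II genes, 4 were higher, 1 lower and 6 not called (6 higher and 1 lower adjusted over the list alone): Cd74 (1.42 ± 0.68), H2-Ab1 (1.15 ± 0.69) and H2-Oa (0.90 ± 0.85; SD, n = 8), and, chosen after their values were seen, H2-Eb1 (0.81) and H2-DMb1 (-0.38). H2-DMb1 stood at 0.12 (limma adjusted p = 0.628) with median centring, and Ccl27a at -0.17 (limma adjusted p = 0.396). The value of H2-Ab1 was uncertain, since its 3 other kept probes gave 0.85, 0.18 and 0.19 without a call (limma adjusted p = 0.242, 0.844 and 0.842), as did a second H2-Oa probe (0.82; limma adjusted p = 0.1). The MHC class II list passed camera with an adjusted p of 0.0065 (adjusted p = 0.447 with an estimated correlation). H2-Oa reached 2.93 in tumor 7, against 0.24 to 0.93 in the others, and had a limma adjusted p of 0.062 with the dye term and best-matching pairs, as H2-DMb1 had 0.159. Of 19 tested MHC class I genes, 4 were higher and 15 not called (7 higher adjusted over the list alone): B2m (1.44 ± 1.23), the peptide trimmer Erap1 (0.85 ± 0.57), H2-M3 (0.77 ± 0.33; SD, n = 8) and, chosen after its value was seen, Psmb10 (0.44). The MHC class I list passed camera with an adjusted p of 0.000208 (adjusted p = 0.417 with an estimated correlation). Its median was 0.68, but 0.79 over the first arrays, 0.07 over the swapped arrays and 0.31 with the dye term and best-matching pairs. The values of H2-M3 and Erap1 were uncertain too, since second probes gave 0.10 and 0.35 without a call (limma adjusted p = 0.879 and 0.114). The value of B2m was uncertain: of its 2 other kept probes, one gave 1.54 and one -1.14, and the limma adjusted p was 0.264 with the dye term and best-matching pairs. In that fit Psmb10 (0.061) and Oasl1 (0.138) also had limma adjusted p-values above 0.05. Of 32 tested interferon response genes, Cxcl9, Cxcl10, Cxcl11 (1.17 ± 0.68, SD, n = 8) and, chosen after their values were seen, Oasl1 (0.86) and Gbp2 (0.56) were higher and 27 not called (5 higher adjusted over the list alone). The interferon list passed camera with an adjusted p of 0.00409 (adjusted p = 0.576 with an estimated correlation). On the first arrays only, the camera adjusted p was 0.0664 and the median over its genes 0.18, against 0.38 over all arrays, so the call rests in part on the swapped arrays whose labels are in doubt. The interferon list median lay above the pool in 5 of 8 tumors and was -1.37 in tumor 6, where the MHC class I median was -0.87.

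Some genes of neutrophils and dendritic cells were also higher, whereas most myeloid genes tested were not called. S100a8 encodes a calcium-binding protein of neutrophils, Il1b an inflammatory cytokine, and Itgax and Ly75 are surface markers of dendritic cells. Of 12 tested neutrophil genes, 5 were higher and 7 not called (11 higher adjusted over the list alone): S100a8 (1.70 ± 1.15), Il1b (1.44 ± 0.73), Cstdc6 (1.33 ± 1.16; SD, n = 8) and, chosen after their values were seen, Fpr2 (1.12) and Retnlg (1.03). The neutrophil list passed camera with an adjusted p of 7.23e-06 (adjusted p = 0.382 with an estimated correlation). Its median was near the pool in tumors 1 (0.061) and 5 (-0.018), against 0.622 to 1.247 in the others. Of 15 tested dendritic cell genes, Ly75 (1.30 ± 0.68), Itgax (0.80 ± 0.29), Batf3 (0.57 ± 0.47; SD, n = 8) and, chosen after its value was seen, Cd86 (0.56) were higher and 11 not called (4 higher adjusted over the list alone). Second probes of Ly75 (0.42) and Itgax (0.32) gave no call (limma adjusted p = 0.0837 and 0.305). The dendritic cell list passed camera with an adjusted p of 0.000502 (adjusted p = 0.382 with an estimated correlation). Of 20 tested complement genes, 5 were higher and 15 not called (5 adjusted over the list alone): C3, the central component (1.25 ± 0.83), Cfb (1.00 ± 0.45), C1s1 (0.82 ± 0.70), C1qc (0.50 ± 0.36; SD, n = 8) and, chosen after its value was seen, C2 (0.78). A second C1s1 probe gave 0.10 without a call (limma adjusted p = 0.898). The complement list passed camera with an adjusted p of 0.00181 (adjusted p = 0.417 with an estimated correlation). Of 10 tested mast cell and eosinophil genes, Hdc, which makes histamine (0.87 ± 0.60), and the tryptase gene Tpsb2 (0.67 ± 0.57; SD, n = 8) were higher and 8 not called (2 adjusted over the list alone). The mast cell and eosinophil list passed camera with an adjusted p of 0.00136 (adjusted p = 0.417 with an estimated correlation). Its median lay below the pool in tumors 1 (-0.118) and 5 (-0.229), against 0.111 to 1.395 in the others. Of 22 tested macrophage genes only C1qc was higher and 21 were not called (0 adjusted over the list alone by limma). The macrophage list passed camera with an adjusted p of 0.0241 (adjusted p = 0.576 with an estimated correlation), and with the dye term and best-matching pairs the macrophage list had a camera adjusted p of 0.0895. Tumors 2 and 3 carried this call (medians of 0.97 and 0.83, against -0.32 to 0.27 in the others), which was lost without tumor 2 (camera adjusted p = 0.165), without tumor 3 (0.115) and on the first arrays only (0.0632). The values of tumors 2 and 3 may share RNA (r = 0.888, array pairs below) and so may not be separate cases. With the dye term and best-matching pairs the genes Retnlg (0.0525), Cstdc6 (0.0863), Cd86 (0.055), C2 (0.0772), Batf3 (0.304), C1s1 (0.0615), C1qc (0.118), Hdc (0.0834) and Tpsb2 (0.214) had limma adjusted p-values above 0.05. The log2 ratio in that fit fell to 0.34 for Batf3 but was 0.81 for C1s1 and 1.23 for Cstdc6.

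**Figure D3:**
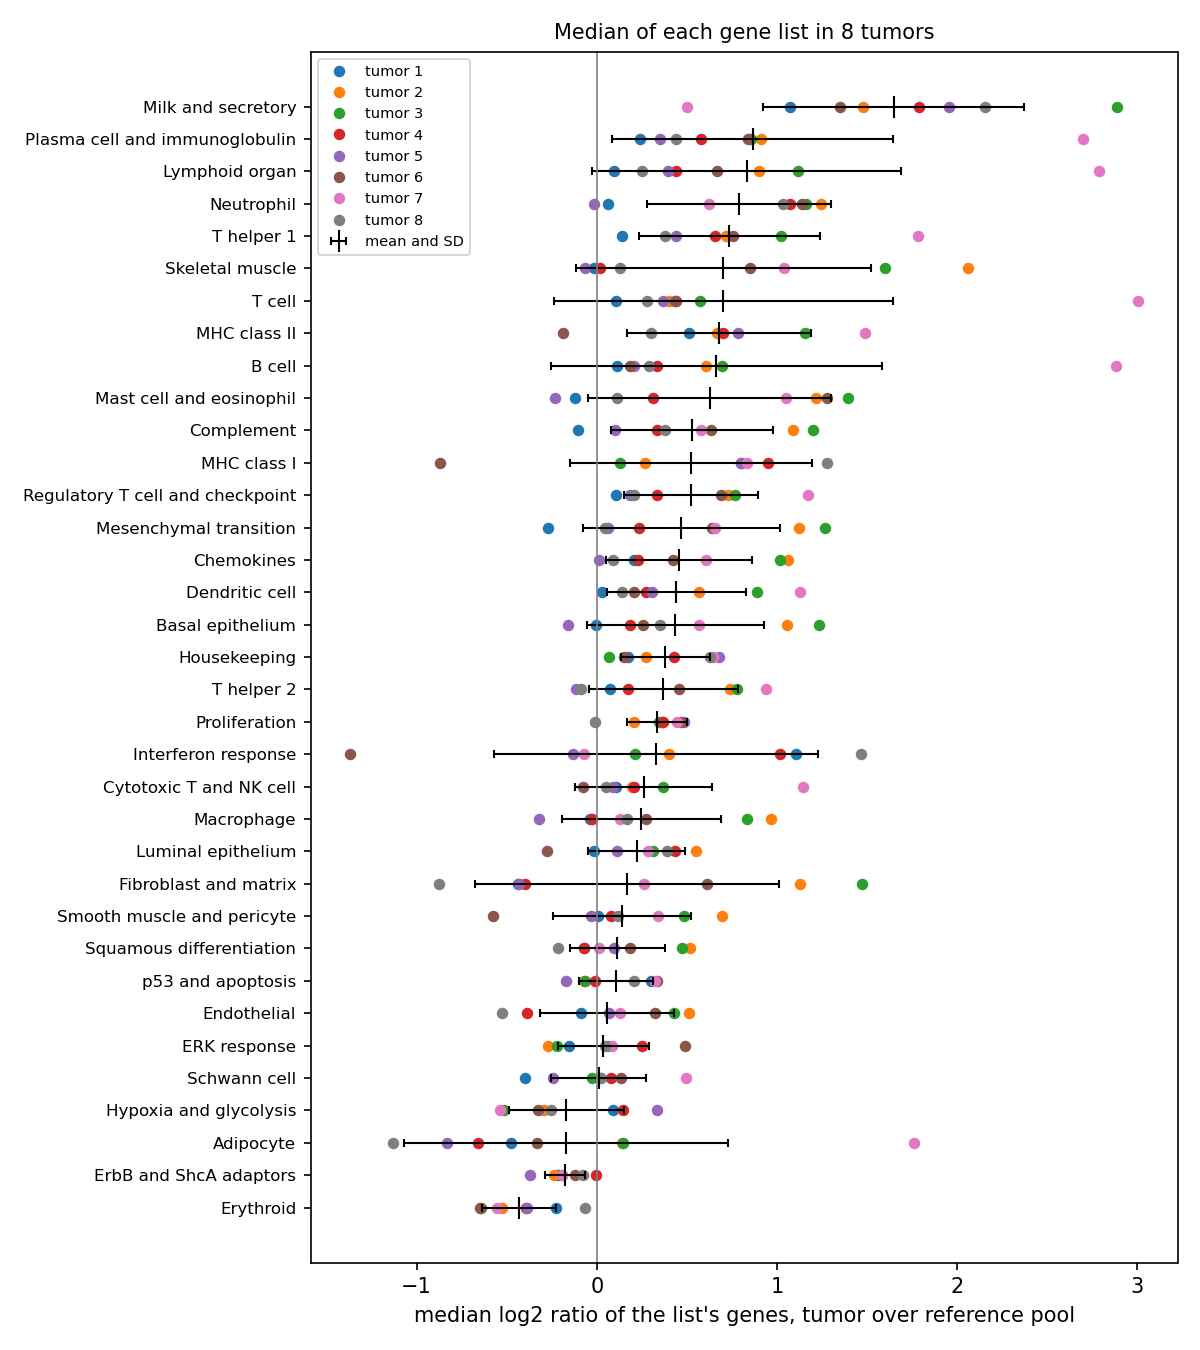
Median log2 ratio of each gene list in each of the 8 tumors, as points with a colour for each tumor and bars for the mean and SD. The milk list lay above the pool in all 8 tumors (0.50 to 2.89), tumor 7 stood apart for the T cell list (3.00), and tumor 6 lay below the pool for the interferon list (-1.37).

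In the epithelial compartment, 11 milk genes were higher, with the basal keratins Krt5 and Krt14, the luminal keratin Krt8 and the oxytocin receptor gene Oxtr beside them. Esr1, the estrogen receptor of hormone-sensing luminal cells, was lower. Of 17 tested milk and secretory genes, 11 were higher and 6 not called (13 higher adjusted over the list alone), led by the beta-casein gene Csn2 (4.59 ± 2.11, SD, n = 7; 24.1-fold), Csn1s1, Glycam1 and Wap. The list median was 1.79 (camera adjusted p = 1.19e-08; adjusted p = 0.382 with an estimated correlation), 1.84 over the first arrays and 1.71 over the swapped arrays. Limma called 8 milk genes higher with the dye term and best-matching pairs. Of 15 tested basal genes, Krt5 (1.29 ± 0.68, SD, n = 7), Oxtr (0.89) and Krt14 (0.83) were higher and 12 not called (6 higher adjusted over the list alone). The basal list passed camera with an adjusted p of 0.0107 (adjusted p = 0.417 with an estimated correlation). Of 20 tested luminal genes, Krt8 (0.84 ± 0.57, SD, n = 8) and, chosen after their values were seen, Krt7 (0.73) and Epcam (0.73) were higher, Esr1 (-0.99 ± 0.84, SD, n = 8) and Gata3 lower and 15 not called (camera adjusted p = 0.148). With median centring Esr1 had a limma adjusted p of 0.0563, and a second Esr1 probe gave -0.22 without a call (limma adjusted p = 0.191). It reached -2.85 in tumor 7, against -1.28 to -0.18 in the others. With the dye term and best-matching pairs the limma adjusted p was 0.0719 for Krt5, 0.107 for Oxtr, 0.25 for Krt14, 0.471 for Krt8, 0.104 for Krt7, 0.666 for Epcam and 0.115 for Esr1, and the basal list had a camera adjusted p of 0.0687. The log2 ratio in that fit fell to 0.29 for Krt8, while Krt5 (1.16), Oxtr (0.84) and Esr1 (-0.88) moved less. The basal call was also lost on the first arrays only (camera adjusted p = 0.0809) and with array weights (0.0933). The basal list median was 1.05 and 1.24 in tumors 2 and 3, which may share RNA, and between -0.16 and 0.57 in the others. In tumors 2 and 3 the skeletal muscle list median was 2.06 and 1.60. Of 12 tested squamous genes 0 were called by limma (2 at an unadjusted p under 0.05).

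The replication licensing genes Mcm2, Mcm3 and Mcm5, the intermediate filament gene Vim and the transition factor gene Snai1 were higher. The red cell genes Alas2, which starts heme synthesis, and Hbb-bt, a beta-globin, were lower. Of 29 tested proliferation genes, 6 were higher and 23 not called (13 higher adjusted over the list alone), with Mcm2 at 0.67 ± 0.30, Mcm5 at 0.58 ± 0.46 and Mcm3 at 0.55 ± 0.14 (SD, n = 8). A second Mcm3 probe gave 0.17 without a call (limma adjusted p = 0.738). The proliferation list passed camera with an adjusted p of 3.78e-05 (adjusted p = 0.382 with an estimated correlation). Of 19 tested mesenchymal transition genes, Vim (1.53 ± 0.95), Snai1 (1.20 ± 0.68) and Tgfbi (0.83 ± 0.53; SD, n = 8) were higher and 16 not called (3 adjusted over the list alone). The mesenchymal list median was 1.12 and 1.27 in tumors 2 and 3, where that of the fibroblast and matrix list was 1.13 and 1.47 and that of the skeletal muscle list 2.06 and 1.60, and between -0.27 and 0.66 in the others. Tumors 2 and 3 may share RNA (r = 0.888, array pairs below). The mesenchymal list passed camera with an adjusted p of 0.00779 (adjusted p = 0.417 with an estimated correlation). The erythroid list was the only one called lower: 3 of 8 tested members were lower, among them Alas2 (-1.26 ± 0.47) and Hbb-bt (-1.14 ± 0.70; SD, n = 8), and 5 not called (3 lower adjusted over the list alone), and the median lay below the pool in all 8 tumors. With median centring Hbb-bt stood at -0.26 (limma adjusted p = 0.577). The erythroid list passed camera with an adjusted p of 0.00494 (adjusted p = 0.382 with an estimated correlation), but on the first arrays only the call was lost (camera adjusted p = 0.0554) and the median over its genes moved from -0.39 to -0.20. Of 12 tested skeletal muscle genes, which mark muscle taken along with the tissue, Mylpf (0.99), Tnnc2 (0.89) and Casq1 (0.65) were higher and 9 not called (6 higher adjusted over the list alone). The skeletal muscle list passed camera with an adjusted p of 0.00409 (adjusted p = 0.433 with an estimated correlation), but not with array weights (0.101) or with both channels above background on all arrays (0.0515). Of 18 tested housekeeping genes, 5 were higher and 13 not called, with Polr2a (0.72) and B2m and, chosen after their values were seen, Actb (0.55) and Tubb5 (0.41) among the higher (7 higher adjusted over the list alone). The housekeeping list passed camera with an adjusted p of 0.0152 (adjusted p = 0.417 with an estimated correlation). The housekeeping median was -0.17 over the swapped arrays, and the list had a camera adjusted p of 0.175 with the dye term and best-matching pairs. In that fit Mcm5 (0.0675), Tgfbi (0.0552), Mylpf (0.259), Tnnc2 (0.138), Casq1 (0.133), Polr2a (0.173), Actb (0.0794) and Tubb5 (0.119) had limma adjusted p-values above 0.05.

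Some signalling genes next to ShcA were called lower, and these calls rest on the scaling: Grb2 links ShcA to the Ras activator Sos, Ptpn11 encodes the phosphatase Shp2, and Grb7 is an adaptor that binds ErbB2. Of 22 tested ErbB and ShcA adaptor genes, Grb7 (-0.83 ± 0.44), Ptpn11 (-0.55), Grb2 (-0.52), Egfr (-0.51) and Pik3ca (-0.45; SD, n = 8), chosen after their values were seen, were lower and 17 not called (camera adjusted p = 0.114). With the dye term and best-matching pairs Egfr (0.0724), Pik3ca (0.16) and Ptpn11 (0.188) had limma adjusted p-values above 0.05. With median centring all 5 did, such as Grb7 (0.359) and Grb2 (0.75). The list median lay below the pool in all 8 tumors (exact sign-flip adjusted p = 0.0228), but the median over its genes turned from -0.24 to 0.105 with median centring. Fry, which asks whether a list moved at all and not more than other genes, put this list lower with an adjusted p of 0.0109. Of 24 tested ERK response genes, Myc (0.61 ± 0.31) and Fosb (0.52 ± 0.35; SD, n = 8) were higher and 22 not called (camera adjusted p = 0.245), and Fosb had a limma adjusted p of 0.31 with the dye term and best-matching pairs. Of the 2 other Myc probes, one gave 0.44 without a call (limma adjusted p = 0.382). Members of the other lists without a call were chosen after their values were seen. In the hypoxia and glycolysis list Bnip3 (-1.74 ± 1.22), Pdk1 (-0.70), Slc2a1 (-0.61) and Ddit4 (-0.51) were lower and Ndrg1 (1.02) and Pkm (0.80) higher of 22 tested. Of these, Pdk1 (0.0818), Slc2a1 (0.256), Ddit4 (0.0752) and Pkm (0.543) had limma adjusted p-values above 0.05 with the dye term and best-matching pairs, and with median centring all 4 lower calls were lost (0.0524 for Bnip3) and Ddit4 turned to 0.22. In the p53 list Trp53inp1 (-1.05) was lower and Pmaip1 (1.12) and Gadd45a (0.44) higher of 18, and Trp53inp1 had a limma adjusted p of 0.0635 with the dye term and best-matching pairs and of 0.124 with median centring. Of 22 fibroblast and matrix genes Thbs2 (1.31 ± 0.29, SD, n = 8) and Col6a2 (0.76) were higher, of 14 smooth muscle genes Mcam (0.53) was higher, and of 17 adipocyte genes 0 were called by limma (2 at an unadjusted p under 0.05). Tumor 7 stood apart in the adipocyte list (1.76), and without it the list median moved from -0.30 to -0.59 and passed camera as lower (adjusted p = 0.0112). Of 22 endothelial genes Flt1 was lower (-0.60 ± 0.49), and of 12 Schwann cell genes 3 were lower, among them S100b (-1.30 ± 0.85) and Mbp (-0.39; SD, n = 8). With median centring Flt1 (0.173), S100b (0.119) and Mbp (0.94) had limma adjusted p-values above 0.05, as had Flt1 (0.104) and Col6a2 (0.243) with the dye term and best-matching pairs. In the endothelial and Schwann cell lists the median (0.05 and 0.09) and the mean (-0.003 and -0.005) differed in sign, so no direction was given.

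Of the 35 lists, 23 passed camera at the preset correlation, 22 higher and 1 lower. With an estimated correlation 0 calls held (camera, 2 lists at an unadjusted p under 0.05), so the set calls rest on the preset value. By fry 10 of them passed, with the dye term and best-matching pairs 20, and without tumors 6 and 7 22. The exact sign-flip test of the tumor medians passed 17 of all 35 lists at an adjusted p of 0.05, and 16 with best-matching arrays averaged. It takes the 8 tumors as independent, which the array pairs below put in doubt. The list medians of the milk, T helper 1, chemokine, regulatory T cell, dendritic cell, lymphoid organ and plasma cell genes lay above the pool in all 8 tumors and also passed fry. Some of these medians barely differed from the pool, such as chemokine in tumor 5 (0.014) and dendritic cell (0.027) and lymphoid organ (0.097) in tumor 1. The housekeeping median also lay above the pool in all 8 tumors (exact sign-flip adjusted p = 0.0228), without passing fry (adjusted p = 0.117). One sign in all 8 tumors is therefore not particular to immune or milk genes.

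Shc1 also showed how the arrays pair, since the 2 arrays with a low Shc1 signal carried the labels of different tumors. The mean correlation between the labelled arrays of tumors 1 to 4 was 0.23 ± 0.11 (SD, n = 4 pairs). Each of 19093 probes was taken as its deviation from the mean of arrays in the same dye orientation. By these deviations the swapped array labelled tumor 1 correlated best with tumor 1 (r = 0.692). The one labelled tumor 2 correlated best with tumor 3 (r = 0.890, own tumor -0.168), the one labelled tumor 3 with tumor 4 (r = 0.562, own tumor -0.589), and the one labelled tumor 4 with tumor 8 (r = 0.805, own tumor 0.078). With best-matching pairs the mean correlation was 0.554, and the correlation within a pair in the fit with a dye term was 0.926, against -0.038 with the labelled pairs. These pairs were picked for their high correlation. The deviations of the swapped arrays cancel out at each probe, so a match of one array lowers the others' correlation with that tumor. Before the subtraction, the swapped arrays labelled tumors 2, 3 and 4 correlated with their own first arrays at 0.10, 0.08 and 0.22. The labelled pairs were kept as fixed before the data were examined, so the values of tumors 2, 3 and 4 each average arrays that did not match and can share RNA with another tumor's value (r = 0.888 for tumors 2 and 3 and 0.84 for tumors 4 and 8). The 8 values were then not independent, and the p-values from them may be too small. The limma calls of named genes that were lost with the other pairing and a dye term stand beside them. On the first arrays alone the tumors correlated with one another at an r from 0.80 (tumors 4 and 5) to -0.0905 (tumors 1 and 6). The averaged values of the 8 tumors had a mean r of 0.404 ± 0.215 (SD), which holds the doubted pairs. First arrays of tumors 6 and 7 had the widest spread of log2 ratios (SD over genes of 1.23 and 1.01), and tumor 6 correlated least with the other tumors (mean r = 0.176).

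**Figure D4:**
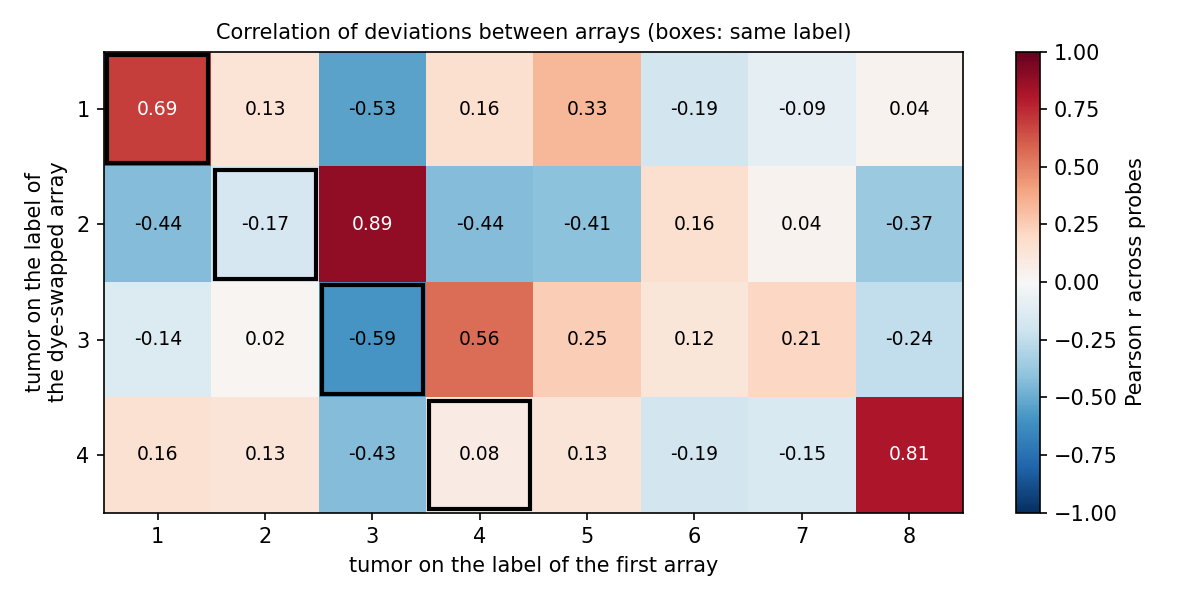
Correlation of the deviations of each of the 4 swapped arrays with the first array of each of the 8 tumors, over 19093 probes. Only the swapped array labelled tumor 1 matched its own tumor best (0.692), and those labelled tumors 2, 3 and 4 matched tumors 3, 4 and 8 (0.890, 0.562 and 0.805).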

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

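The tests of explanations in this part were chosen after the results were seen, whereas the search for a tumor far from the others followed a fixed criterion. In 117 results, each a named gene, a probe of Shc1 or Erbb2 or a list median over the 8 tumors, the gap between the most extreme tumor and its neighbour was compared with the whole range. The gap passed Dixon's critical value for 8 samples in 14 results. Tumor 7 was the extreme one in 12 of them and tumor 5 in 2. Chance passes about 5% of independent results. These results share the same tumors and in part the same genes, so that share is no measure of chance here.

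Tumor 7 stood far above the others for lymphocyte genes. Its list median was 3.004 for the T cell list (others 0.109 to 0.575), 2.884 for B cell (0.113 to 0.694), 2.785 for lymphoid organ (0.097 to 1.115), 2.697 for plasma cell and immunoglobulin (0.240 to 0.912) and 1.147 for cytotoxic T and NK cell genes (-0.078 to 0.370). Among single genes, the Igkv1 segment of the report reached 4.634 (others 1.110 to 2.739), Cxcr6 2.830 (0.20 to 1.289), Icos 3.299 (0.251 to 1.573), Mzb1 3.453 (0.577 to 1.781) and H2-Oa 2.925 (0.235 to 0.926). The adipocyte list median was 1.763 in tumor 7 (others -1.133 to 0.144). Esr1 was at -2.848 in tumor 7 (others -1.282 to -0.176).

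Lymph node tissue in the sample is a candidate explanation for tumor 7. It needs the genes of lymphoid organs to rise along with T and B cells, and the lymphoid organ list stood 2.346 above the median of the other tumors, with gaps of 2.601 for the T cell and 2.595 for the B cell list. A lower share of tumor epithelium would raise macrophage genes too, and these stood at -0.040 relative to the median of the others. This does not decide it, since other lists were mixed. Adipocyte genes stood at 2.238, endothelial at 0.063, luminal at -0.026 and milk genes at -1.289 relative to that median. Lymph node tissue would itself lower the share of epithelium. A lymphocyte infiltrate of the tumor cannot be told apart from lymph node tissue: the cytotoxic T and NK cell list stood 1.041 above the others. Within the lymphoid organ list, Chst4 stood at 0.034 in tumor 7 (median of the others 0.052) and Clec4g at 0.916 (0.032). Both genes were dim. All tested genes of that list except Chst4 stood above the median of the others, and these values do not separate the 2 sources.

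In tumor 5, Odam was at -0.219 (others -3.980 to -2.280) and Scgb1b27 at -0.460 (others -3.469 to -2.346).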

How the results depend on the processing

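The pairing of swapped arrays by best match, alone or with a dye term, and the fit without tumors 6 and 7 were tests chosen after the results were seen. Against 3499 genes called, 964 past 2-fold and 23 lists, array weights called 7686 genes and an adjusted p under 0.01 called 1138 (549 past 2-fold), fewer by its construction. Feature Extraction's processed signals put 1644 genes past 2-fold. Best-matching arrays averaged called 2266 genes, and best-matching pairs with a dye term 1636 (618 past 2-fold). Leaving out each tumor in turn gave 1971 (without tumor 4) to 4546 genes (without tumor 6), with 2239 without tumor 8. Camera with an estimated correlation passed 0 lists (2 at an unadjusted p under 0.05) and fry 11. The list shift per tumor passed 17 lists, 16 with best-matching arrays averaged, and 0 with tumors 1 to 4 only, where 4 tumors are too few to pass. Agreement of the swapped arrays was 0.23, 0.043 with median centring and 0.554 with best-matching pairs. With outlier spots kept, Pik3c2g turned to 0.997, through a brighter probe, and Cd3e to 1.009. Where no construction is named, the cause was not tested. Under the alternatives of processing and samples, 897 list results stayed the same, which counts the 12 uncalled lists where they stayed uncalled. Of the rest, 34 lost a call, 14 gained one and 0 called ones reversed. The estimated correlation lost 23 and fry 13 of the 23 calls. For the named genes 1974 results stayed the same and 248 lost a call. The call of Shc1 did not change in any alternative run on it. Aquantile leaves the ratios within an array as they are, tests nothing and is not counted. Every alternative planned was run. Signal over background limits dim genes: 30838 of 41174 probes could be tested.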

Other observations

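The families and tests of explanations in this part were chosen after the results were seen. Kappa variable segments, which build antibody light chains, were higher as a family. Of 13 tested Igkv genes, 12 were higher and 1 not called, with a median log2 ratio of 2.01 (2.03 with median centring), 8 of 8 tumors above the pool and a camera adjusted p of 7.14e-09 (adjusted p = 0.874 with an estimated correlation). With the dye term and best-matching pairs, 9 of them were called higher. These segments share much sequence, so the values of single members are uncertain. Interleukin genes and some of their receptors, grouped by symbol, carry signals between leukocytes. Of 50 tested, 11 were higher, among them Il20ra (1.15 ± 1.00, SD, n = 8), 1 was lower and 38 were not called. Receptors with longer symbols, such as Il12rb1, were not in this group. The family passed camera with an adjusted p of 2e-04 (adjusted p = 0.874 with an estimated correlation), and 4 genes were called higher and 0 lower by limma with the dye term and best-matching pairs. The lower one was Il15, with a limma adjusted p of 0.582 in that fit. Of 12 tested Serpina genes, protease inhibitors of the acute phase, the interferon-responsive Serpina3g (1.60 ± 0.71), Serpina3f (1.19 ± 0.93) and Serpina3m (0.66 ± 0.52; SD, n = 8) were higher and 9 not called. Serpina3m had a limma adjusted p of 0.123 with the dye term and best-matching pairs. The Serpina family passed camera with an adjusted p of 0.00181 (adjusted p = 0.874 with an estimated correlation).

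A few Osbpl and Chmp genes were lower, and most of these calls rest on the scaling. Osbpl genes encode oxysterol-binding carriers, and of 10 tested Osbpl6 (-1.31 ± 0.53), Osbpl5 (-0.88 ± 0.42), Osbpl9 (-0.80 ± 0.54) and Osbpl1a (-0.71 ± 0.24; SD, n = 8) were lower and 6 not called. The family passed camera with an adjusted p of 0.0311 (adjusted p = 0.874 with an estimated correlation), and its median was -0.28, or -0.03 with median centring, which kept only Osbpl6 of the 4 under a limma adjusted p of 0.05. Chmp genes encode parts of the complex that pinches off membranes, and of 10 tested Chmp4c (-2.22 ± 1.05), Chmp5 (-0.97 ± 0.42) and Chmp2a (-0.57 ± 0.21; SD, n = 8) were lower and 7 not called. The family passed camera with an adjusted p of 0.0326 (adjusted p = 0.874 with an estimated correlation), with a median of -0.53, or -0.08 with median centring, which kept only Chmp4c of the 3 under a limma adjusted p of 0.05 and turned Chmp2a to 0.03. With the dye term and best-matching pairs Osbpl9 (0.171) and Chmp2a (0.0756) had limma adjusted p-values above 0.05. In all, 17 of 194 families passed camera, 13 of them higher, with adjusted p-values of 0.874 or 0.886 with an estimated correlation. The olfactory receptor family (Olfr) passed as higher with a camera adjusted p of 1.66e-05, although of 298 genes 0 were higher and 3 lower. Its median was 0.20 over the first arrays and -0.15 over the swapped arrays. A camera call can thus rest on a small shift that differs between these arrays.

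Ribosomal protein genes (Rps and Rpl) differed between the first and the swapped arrays, which differ in slide and dye orientation together: of 80 tested, 26 were higher and 1 lower, their median was 1.33 over the first arrays and -1.01 over the swapped arrays, and 0 were called with the dye term and best-matching pairs. Of 1589 transcripts named only by an AK clone, 31 were higher and 395 lower, with a median of -0.34 over the first arrays and 0.003 over the swapped arrays. With the dye term and best-matching pairs 17 of these were higher and 127 lower. Along the chromosomes, in order of position, of the 51 genes around Ankrd17 on chr 5, 12 were past 2-fold, among them the casein genes Csn1s1 and Csn2, Jchain, Cxcl9, Cxcl10 and Cxcl11, which were higher, and Odam, which was lower.

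Wrongly labelled swapped arrays are a candidate explanation for the low agreement between the arrays of a tumor. This mislabelled arrays explanation needs arrays that match another tumor. In deviations from the mean of each dye orientation, 3 of the 4 swapped arrays correlated above 0.5 with the first array of another tumor and less with their own. Before that subtraction these 3 pairs correlated at 0.797, 0.304 and 0.649, against 0.10, 0.08 and 0.22 with their own tumors. For the array labelled tumor 3, the first array of tumor 7 came close (0.225), so its match is less clear. Array noise is argued against, since even the weakest of the 4 best matches had a correlation of deviations of 0.561. This holds least firmly for that weakest match, of the array labelled tumor 3. An effect of slide or dye that all swapped arrays share is argued against as the source of these matches. The same deviations leave out the mean of each orientation, and in them the 3 arrays correlated with another tumor more than with their own by at least 0.727. That lead can be inflated. The deviations of the swapped arrays cancel out at each probe, so a match of one array lowers the others' correlation with that tumor. Such an effect can still lower the agreement before subtraction, where swapped arrays of different tumors correlated at up to 0.672. No biological explanation was tested.

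Milk genes could be higher because the tumors labelled ShcA-null kept more secretory differentiation, because the pool was low in these genes, or because normal mammary tissue was taken along. A pool low in milk genes cannot be told apart from the other possibilities, since all 8 tumors were set against 1 pool (mean of the tumor medians 1.648). Fatty mammary tissue as the source in every tumor is argued against, because the adipocyte median lay below the pool in 5 of the 8 tumors. Tumor 7, with the highest adipocyte median (1.763), had the lowest milk median (0.501). In tumors 2 and 3, with adipocyte medians of 0.139 and 0.144, it was not excluded. An effect of slide or dye is argued against by a median of 1.711 over the swapped arrays, against 1.836 over the first arrays.

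A segment of another strain around the targeted gene could change its neighbours. Of the 51 genes at Shc1, 1 (Fam189b) was past 2-fold, where 82.2% of 14781 such windows held as many or more. Genes past 2-fold were thus not crowded there, but this count cannot exclude a segment that changes few genes or changes them by less.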
